A study of Drosophila melanogaster with 6 samples.

How the data were processed

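RNA was measured by RNA-seq in whole adult male flies, 3 libraries labelled control and 3 labelled dERR mutant. Per the labels' protocols, total RNA was poly(A)-selected and made into stranded mRNA libraries. Novoalign, DESeq2 and the genome build dm3 are named in the submitters' processing notes, without versions or settings. The counting tool, its strand setting and the annotation release are not given in the sources used here.

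The authors deposited one table of 13035 genes. Its 6 library columns hold a signal that is never negative: normalized counts, which per the values are read counts of the authors divided by one size factor per library. The deposited table also holds the authors' own comparison, per the file headers a shrunken log2 fold change, its maximum likelihood value, its standard error, a p-value and an adjusted p-value as DESeq2 writes them. For 8 genes the deposited table gives no p-value. In each column every value was a whole multiple of one constant (tolerance 1e-06), so total reads per library could be worked out, from 13987814 to 16102936. In 3 columns that constant was too close to 1 for the recovered reads to be accepted by the check of units, so no count model was fitted. The planned edgeR quasi-likelihood test was therefore replaced by the planned fallback for tables without counts, limma-trend on log2(normalized count + 1).

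The fit used limma 3.58.1 in R 4.3.3, with all 6 libraries, a group term only, no filter, a trended variance and Benjamini-Hochberg adjustment over all 13035 genes, and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of genes with few reads. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. No paired fit was made, because the labels give no pairing and replicate numbers only name libraries. Pairs of libraries of a group differed by 7.13 to 13.68 in chi-square per gene over genes with at least 20 reads. Sampling alone gives a value of 1, so none was counted as the same library deposited again. Repeat preparations of the same RNA were not excluded by this check.

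The method was tested on simulated data of the same size, drawn from the real means with the same dispersion for all genes. The 200 changed genes were taken only from those above a minimum mean. The method recovered 62 of 67 genes changed 1.5-fold (92.5%), 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 11 of its 206 calls (5.3%) were false. These shares do not cover genes with few reads or a larger spread. In 100 simulated unchanged lists of 20 genes the list test (camera, preset correlation) gave an unadjusted p under 0.05 in 5. Simulated genes varied independently of each other. In the data the estimated correlation was 0.59 for glycolysis and 0.67 for oxidative phosphorylation. The simulation therefore does not test the list p-values where members vary together.

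Before the data were examined, 25 gene lists were fixed, with 591 members, of which 552 were measured. They are the lists reported by name in the results. Each list was tested by camera with a preset inter-gene correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the 25 lists. Of 18 lists with a camera adjusted p under 0.05, 0 kept it with an estimated correlation, where 5 had an unadjusted p under 0.05 and the lowest adjusted p was 0.21. Fry gave an adjusted p under 0.05 for 12 lists moving one way on balance and for 21 lists changing in either direction. In 2 lists, insulin and mitochondrially encoded, the median and mean differed in sign.

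Genes are named by a rule fixed in advance: ERR; up to 15 genes with the largest rise and 15 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between groups; from each list up to 4 members per direction with the smallest adjusted p, or the 2 most abundant where none passed; all glycolysis members; and all nuclear receptors past the threshold. The text names part of the genes this rule takes. Symbols are those of the deposited table, with current symbols in brackets from a reference name table in which 12526 of the 13035 identifiers were found. Coordinates are those of the deposited table, on dm3. The reference annotation given here is on another build and served only for names and strands.

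Genes that overlap cannot be told apart where the counting did not use strand. In the deposited coordinates, the named genes ERR, Mal-B1, TpnC4, Pgk, Rpi, yip2, LysP, PGRP-LB, TotX, Cyp6g2, cry, CG11594, Hnf4, Eip75B, ninaA, Hsp22 and Hsp67Bb overlap a gene with at least 20% of their level, and their values are uncertain to that extent. Close paralogs (Gapdh1 and Gapdh2, the lysozymes, the Jon65A peptidases) may share reads. Across the table, 146 overlapping pairs of genes had levels within 2% of each other in each library, 15 of them with a called gene first, which points to the same reads counted for both.

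The alternatives tried were a pseudocount of 0.1, a mean of at least 1, a filter of 5 CPM in 3 libraries, upper-quartile scaling, library size with and without the 20 most abundant genes, limma-voom with the deposited scaling, stricter thresholds, an estimated inter-gene correlation and leaving out each library. A robust variance prior, quantile normalization and scaling to ribosomal protein genes were added after the data were seen.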

Results

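Poly(A)-selected RNA of whole adult male Drosophila melanogaster was sequenced in 6 libraries, 3 of flies labelled control and 3 of flies labelled dERR mutant, all collected on day 6 of adult life. Estrogen-related receptor (ERR) is the fly's single member of an orphan nuclear receptor family known as a regulator of energy metabolism. Both groups carried a conditional dERR allele over a mutant dERR allele together with a heat-inducible FLP recombinase. Flies of the mutant group were heated for 1 h on days 5 and 6 after egg laying to switch the recombinase on, and control flies were not heated. The deposited table listed 13035 genes as normalized counts, and the control libraries held 14325008, 16102936 and 14985562 gene-assigned reads and the mutant libraries 14780864, 13987814 and 14363697, worked out from the step between values. The most abundant gene, the cytochrome P450 Cyp4g1, took 2.84 to 3.02% of reads in control and 1.96 to 2.26% in mutant libraries. Principal component 1 held 56.6% of the variance and separated the groups.

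The targeted gene was lower in each mutant library than in each control library. ERR (FBgn0035849; chromosome arm 3L, 8176460 to 8179771, dm3) had normalized counts of 373, 497 and 539 in the control libraries and 112, 119 and 107 in the mutant libraries. The means were 470 ± 86.5 and 113 ± 6.01 (SD, n = 3 each). On the log2(normalized count + 1) scale ERR fell by 2.03 ± 0.13 (SE), or 4.09-fold, with an adjusted p of 3.58e-06 (limma). In the authors' deposited table the change of ERR was -2.06 as a maximum likelihood log2 fold change, with an adjusted p of 1.25e-35. Which exons the mutant alleles lack is not given in the sources used here, so which part of the remaining ERR reads comes from an altered transcript is not known.

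The comparison of mutant with control flies addressed which adult transcripts depend on ERR, in particular those of glycolysis and lipid synthesis. In mutant flies the genes of sugar breakdown, glycogen and trehalose metabolism and the pentose phosphate pathway were lower, and nuclear genes of the mitochondrial respiratory chain were higher. All 14 measured glycolysis genes fell, by a median of 1.04 on the log2 scale, while 47 of 53 oxidative phosphorylation genes rose, with a median of 0.43. Seminal fluid genes of the accessory gland list fell as well (20 of 21), and 16 of 24 muscle genes rose. Across all genes, 1851 of 13035 passed an adjusted p of 0.05 (limma), 617 higher and 1234 lower in the mutant. Changes of 2-fold or more were mostly decreases, with 305 genes lower and 36 higher.

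Glycolysis genes fell at each step of the pathway from hexose phosphorylation to lactate. The glyceraldehyde-3-phosphate dehydrogenase Gapdh2 (FBgn0001092; X, 15762177 to 15763694, dm3) dropped from 10418 ± 1019 to 2617 ± 256 normalized counts (SD, n = 3 each), a log2 change of -1.99 ± 0.10 (SE; adjusted p = 4.26e-07, limma). Phosphoglycerate mutase Pglym78 changed by -1.78 ± 0.09, phosphoglycerate kinase Pgk by -1.76 ± 0.08 and glucose-6-phosphate isomerase Pgi by -1.52 ± 0.08 (log2, SE). Gapdh1 and enolase (Eno) changed by -1.38 ± 0.09 and -1.31 ± 0.08, lactate dehydrogenase ImpL3 by -1.06 ± 0.10 and aldolase (Ald) by -1.02 ± 0.10. Smaller falls were measured for Pfk (-0.91 ± 0.09), Tpi (-0.90 ± 0.07), the hexokinase Hex-C (-0.79 ± 0.09) and glycerol-3-phosphate dehydrogenase Gpdh (-0.71 ± 0.08). Pyruvate kinase (PyK, -0.33 ± 0.09) and Hex-A (-0.29 ± 0.07) moved least. The calls of PyK and Hex-A ended under scaling to library size (adjusted p = 7.05e-02 and 7.68e-02, limma). The call of Hex-A also ended without any one library other than control 3, and that of PyK without any one library other than control 2. Adjusted over the list alone, all 14 genes passed as well. The list stood apart from other genes in camera at an adjusted p of 2.26e-20, and at an adjusted p = 0.21 with an estimated correlation. The testis-enriched paralogs of glycolytic enzymes had a median log2 change of 0.16 (-0.02 with scaling to ribosomal protein genes), and 0 of 11 passed the test in limma-trend and in limma-voom, with 4 at an unadjusted p under 0.05 (camera adjusted p = 4.72e-03; adjusted p = 0.52 with an estimated correlation). With library size alone 3 of them were called higher, without control replicate 2 the number was 1, and their camera call ended without control replicate 1 (adjusted p = 6.83e-02).

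**Figure D1:**
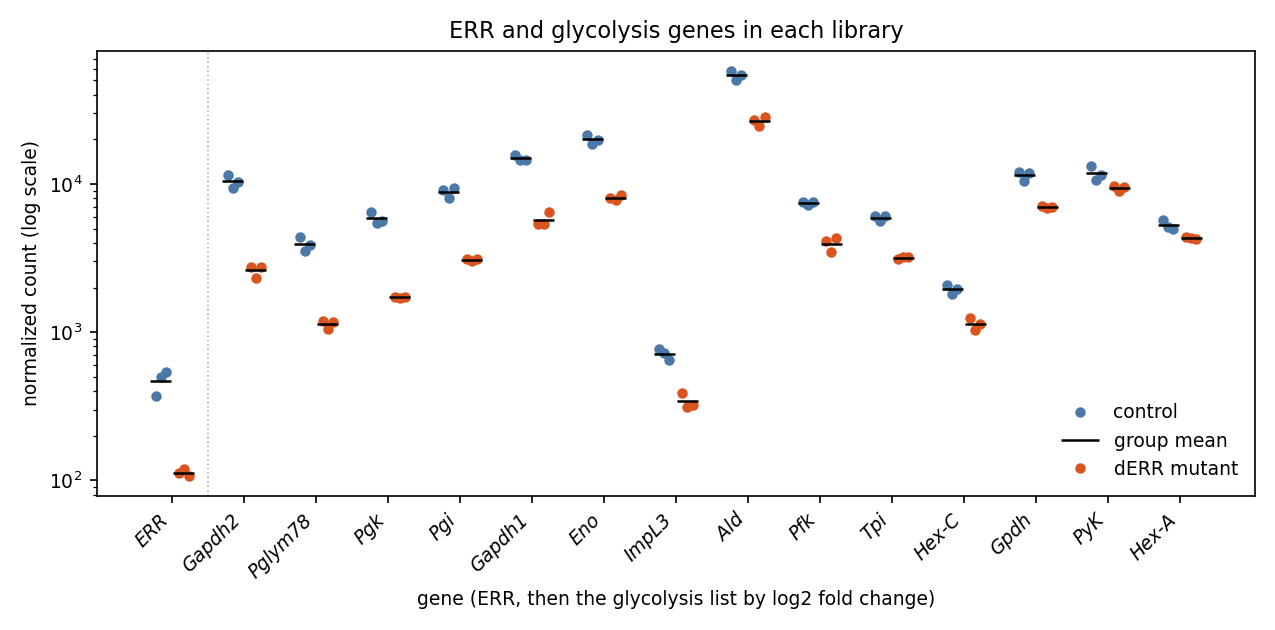
Normalized counts, on a log scale, of ERR and of the 14 genes of the glycolysis list in each of the 6 libraries, ordered by log2 fold change; points are libraries (blue control, orange dERR mutant) and black bars are group means. For each gene the 3 mutant libraries lie below the 3 control libraries, from 4.09-fold lower for ERR and 3.98-fold for Gapdh2 to -0.29 on the log2 scale for Hex-A.

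Genes of enzymes that store and mobilize sugar were also lower. Of 9 measured trehalose and glycogen genes 8 fell (8 adjusted over the list alone), with a list median of -1.54. The glycogen branching enzyme CG33138 changed by -2.23 ± 0.10 (log2, SE), the UDP-glucose pyrophosphorylase UGP by -2.11 ± 0.09, phosphoglucomutase (Pgm) by -2.04 ± 0.07 and the glycogen synthase CG6904 by -1.54 ± 0.09. In the pentose phosphate and NADPH list 7 of 9 genes fell (7 adjusted over the list alone), with a median of -0.96. Transaldolase (Tal) changed by -2.15 ± 0.09, the transketolase CG8036 by -1.45 ± 0.09, ribose-5-phosphate isomerase (Rpi) by -1.04 ± 0.08 and glucose-6-phosphate dehydrogenase (Zw) by -0.96 ± 0.08. Camera gave adjusted p-values of 1.51e-11 for trehalose and glycogen and 1.51e-10 for the pentose phosphate list. With an estimated correlation these were adjusted p = 0.24 and adjusted p = 0.21.

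Nuclear genes of oxidative phosphorylation ranged in log2 change from -0.07 to 0.75, and 6 of 53 were not called. The complex I subunit CG5703 (ND-24) increased from 2757 ± 106 to 4604 ± 231 normalized counts (SD, n = 3 each), a log2 change of 0.74 ± 0.07 (SE; adjusted p = 5.31e-05, limma). The complex I subunits CG5548 (0.65 ± 0.07) and ND42 (0.63 ± 0.07) and the ATP synthase subunit l(1)G0230 (0.62 ± 0.07) rose likewise. All 47 calls stood adjusted over the list alone. The muscle list rose alongside, with 16 of 24 members higher and the same median of 0.43. Scaled to ribosomal protein genes, a setting chosen after the data were seen, 22 of the 53 oxidative phosphorylation genes and 10 of the 24 muscle genes were called higher, with 1 muscle gene lower. Camera gave an adjusted p of 7.51e-29 for the list, and adjusted p = 0.27 with an estimated correlation. Of the 11 mitochondrially encoded genes 0 passed in limma-trend or limma-voom, and 2 had an unadjusted p under 0.05. Without control replicate 1, 1 of them was called lower. Their most abundant members mt:CoI and mt:CoIII had log2 changes of -0.13 ± 0.11 and -0.06 ± 0.16, and the list's median (-0.04) differed in sign from its mean (0.08).

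In the pyruvate dehydrogenase and TCA cycle list 11 of 22 genes rose and 2 fell (14 and 2 adjusted over the list alone). The succinate dehydrogenase subunits SdhC and SdhB increased by 0.61 ± 0.07 and 0.59 ± 0.08 (log2, SE), and the isocitrate dehydrogenase subunit l(1)G0156 by 0.43 ± 0.08. The genes that fell act outside the cycle proper: Mdh1, the cytosolic malate dehydrogenase, changed by -1.21 ± 0.08 and CG1516, pyruvate carboxylase, by -0.74 ± 0.08. Camera gave the list an adjusted p of 1.13e-04, and adjusted p = 0.44 with an estimated correlation. The number of genes called higher was 7 without mutant replicate 3 and 2 with scaling to ribosomal protein genes.

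Genes of fat breakdown and of fat transport were mostly lower. Of 22 measured beta-oxidation genes 15 fell (16 adjusted over the list alone; median -0.36), among them the acyl-CoA dehydrogenase CG12262 (Mcad, -1.07 ± 0.10), the thiolase yip2 (-0.81 ± 0.09) and the acyl-CoA oxidase CG5009 (-0.66 ± 0.09). Without control replicate 3 the number was 8. In the list of lipolysis, lipid storage and transport 8 of 14 genes fell and 2 rose (9 and 2 adjusted over the list alone). The number higher was 1 without control replicate 3, without mutant replicate 1 and with scaling to ribosomal protein genes. The lipophorin precursor Rfabg changed by -1.93 ± 0.12, the lipid droplet protein Lsd-1 by -1.69 ± 0.15 and the lipases CG8093 and Lip4 by -1.56 ± 0.13 and -1.51 ± 0.15. The triglyceride lipase brummer (bmm) went the other way, at 0.55 ± 0.10. Fatty acid and triglyceride synthesis genes were split, with 8 of 21 lower and 3 higher (10 and 3 adjusted over the list alone; median -0.22). The fatty acid synthase CG17374 changed by -1.20 ± 0.12, ATP citrate lyase (ATPCL) by -0.61 ± 0.11 and the acyltransferase CG4753 by -0.76 ± 0.10. The sterol regulatory element binding protein HLH106 (0.42 ± 0.07) and the glycerol-3-phosphate acyltransferase CG5508 (0.39 ± 0.07) rose. Without mutant replicate 3 the number of synthesis genes called lower was 5, and scaled to ribosomal protein genes 0 were called higher by limma. Camera adjusted p-values were 6.09e-09 for beta-oxidation, 5.82e-05 for lipolysis, storage and transport and 4.72e-03 for synthesis. With an estimated correlation they were adjusted p = 0.27, adjusted p = 0.27 and adjusted p = 0.44 in that order.

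Genes that respond to feeding and insulin moved in both directions. Of 17 measured genes 4 rose and 5 fell (4 and 6 adjusted over the list alone). The list was not shifted in one direction against other genes (camera adjusted p = 0.919), a test in which opposite changes can cancel. Fry for changes in either direction, which makes no comparison with other genes, gave an adjusted p of 1.70e-04. The list's median was 0.01 and its mean -0.22. Phosphoenolpyruvate carboxykinase (Pepck; FBgn0003067; 2R, 14424271 to 14426924, dm3) dropped from 12857 ± 4246 to 872 ± 246 normalized counts (SD, n = 3 each), a log2 change of -3.87 ± 0.24 (SE; adjusted p = 2.95e-06, limma). The gluconeogenic fructose-1,6-bisphosphatase (fbp) changed by -1.60 ± 0.16. Thor, the 4E-BP translation inhibitor, rose by 1.70 ± 0.12 and the kinase Lk6 by 0.55 ± 0.09. Without control replicate 3, 2 members were called higher and 3 lower, without mutant replicate 1 the number higher was 2, and without control replicate 1 the number lower was 3. Scaled to ribosomal protein genes 2 were called higher.

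Gut and detoxification genes changed unevenly. Among 28 digestive peptidases and lysozymes 17 fell and 4 rose (19 and 5 adjusted over the list alone; camera adjusted p = 2.18e-05; adjusted p = 0.28 with an estimated correlation). The serine peptidases Jon65Ai and Jon65Aii changed by -1.72 ± 0.20 and -1.15 ± 0.13 and thetaTry by -0.69 ± 0.07, whereas the lysozymes LysP and LysD rose by 0.73 ± 0.09 and 0.46 ± 0.07. Scaled to ribosomal protein genes 2 were called higher. Of 14 digestive carbohydrases 4 fell and 2 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.37). The maltase Mal-B1 increased from 362 ± 2.82 to 2173 ± 279 normalized counts (SD, n = 3 each), a log2 change of 2.58 ± 0.09. Without one library the number of carbohydrases called lower ran from 1, without control replicate 3, to 7, without mutant replicate 1. Leaving out control replicate 1, control replicate 2 or mutant replicate 3 gave 2, as did a robust variance prior, and 7 were called lower and 1 higher with scaling to ribosomal protein genes. Without mutant replicate 1 the carbohydrase list passed camera (adjusted p = 6.49e-03). In the detoxification and oxidative stress list 21 of 42 genes fell and 1 rose (26 and 2 adjusted over the list alone; camera adjusted p = 1.41e-07; adjusted p = 0.29 with an estimated correlation). The cytochrome P450 genes Cyp6w1 and Cyp6g2 changed by -1.74 ± 0.12 and -0.99 ± 0.14 and the mitochondrial superoxide dismutase Sod2 rose by 0.40 ± 0.07. The number lower was 12 without control replicate 3 and 13 without mutant replicate 3. The number higher was 2 without mutant replicate 3, with library size, with or without the 20 most abundant genes, and with quantile normalization, and 0 with scaling to ribosomal protein genes. Of 30 immune genes 9 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 1.28e-03; adjusted p = 0.46 with an estimated correlation), among them PGRP-LB (-0.64 ± 0.10) and TotX (-1.78 ± 0.26). Without control replicate 1 the number lower was 5 and camera gave an adjusted p of 0.171, as it gave 0.167 with scaling to ribosomal protein genes. The number lower was also 5 with a robust variance prior. The number higher was 0 with the filter of 5 CPM and without control replicate 1, control replicate 2, mutant replicate 1 or mutant replicate 3.

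Markers of tissue makeup, heat and time of day were measured in the same libraries. The accessory gland list fell in 20 of 21 genes (20 adjusted over the list alone; median -1.19; camera adjusted p = 5.45e-26; adjusted p = 0.21 with an estimated correlation). The seminal fluid genes Acp26Aa, Dup99B and Est-6 changed by -1.38 ± 0.09, -1.32 ± 0.09 and -1.42 ± 0.10 (log2, SE). Whether each member of the list is made in the accessory gland was not examined. In the muscle list 16 of 24 genes rose (16 adjusted over the list alone; camera adjusted p = 4.55e-11; adjusted p = 0.29 with an estimated correlation). Act88F, the actin of the indirect flight muscle, rose by 2.11 ± 0.09 and the flight muscle troponin C TpnC4 by 1.81 ± 0.13, with Mlc1 and up at 0.69 ± 0.08 and 0.67 ± 0.08. In the larval fat body list 3 of 4 genes measured of 9 listed fell (3 adjusted over the list alone, median -3.08). Camera gave an adjusted p of 9.55e-04, and adjusted p = 0.21 with an estimated correlation. The list holds larval serum protein, Fbp and Sgs genes, and which tissue of these adults made their transcripts was not examined. The genes that fell were the larval serum protein genes Lsp2, Lsp1beta and Lsp1alpha. Among them Lsp1alpha had a mean of only 0.35 CPM. Its call ended without control replicate 1 (adjusted p = 8.34e-02, limma) and without control replicate 3 (adjusted p = 1.22e-01, limma). Testis genes had a median of 0.15, which became -0.03 with scaling to ribosomal protein genes, and 0 of 26 passed in limma-trend or limma-voom (7 at an unadjusted p under 0.05; camera adjusted p = 7.50e-03; adjusted p = 0.59 with an estimated correlation). The camera call of testis genes ended without control replicate 1 (adjusted p = 0.219) and without mutant replicate 2 (adjusted p = 5.05e-02), and 6 members were called higher with library size alone. The number higher was 2 with upper-quartile scaling, library size without the 20 most abundant genes and quantile normalization, as without mutant replicate 1, and 1 with a robust variance prior. Of 16 photoreceptor genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; median 0.06, and -0.12 with scaling to ribosomal protein genes, where 1 rose and 4 fell). The single fall, ninaA, was lost (0 lower) under the other 4 scalings and without any one library other than mutant 2. Of 7 female reproductive genes 1 fell (1 adjusted over the list alone), the yolk protein gene Yp3 at -0.62 ± 0.16, and that call ended without control replicate 1, control replicate 2 or mutant replicate 1. In the heat shock list 4 of 17 genes rose (4 adjusted over the list alone; camera adjusted p = 1.33e-02; adjusted p = 0.44 with an estimated correlation). Its members Hsp22 and Hsp67Bb, which overlap, rose by 0.55 ± 0.09 and 0.53 ± 0.09, and l(2)efl by 0.37 ± 0.08. Camera gave an adjusted p of 8.63e-02 for that list without mutant replicate 1, and 2 members were called higher and 1 lower with scaling to ribosomal protein genes. Of 9 circadian genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), with cwo at 0.49 ± 0.08 and cry at -0.45 ± 0.07. Camera, in which opposite changes can cancel, gave an adjusted p of 0.377, and fry for either direction an adjusted p of 2.52e-04. With scaling to ribosomal protein genes 0 circadian genes were called higher by limma and 3 lower. A difference between the groups in time of collection was not tested. Of 18 other nuclear receptors 0 passed in limma-trend or limma-voom (3 at an unadjusted p under 0.05), with Hnf4 at -0.03 ± 0.07. Without mutant replicate 2, 1 of them was called lower, and 3 were with scaling to ribosomal protein genes. Of 93 cytoplasmic ribosomal protein genes 3 rose (2 adjusted over the list alone; median 0.16, -0.02 with scaling to these genes), led by RpL24-like at 0.94 ± 0.09. The number higher was 39 with scaling to library size, 26 without the 20 most abundant genes, 21 with quantile normalization, 9 with upper-quartile scaling and 1 with scaling to these genes. Without one library it ran from 2 to 11, the highest without control replicate 1. Camera gave these genes an adjusted p of 2.20e-10, and adjusted p = 0.46 with an estimated correlation.

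**Figure D2:**
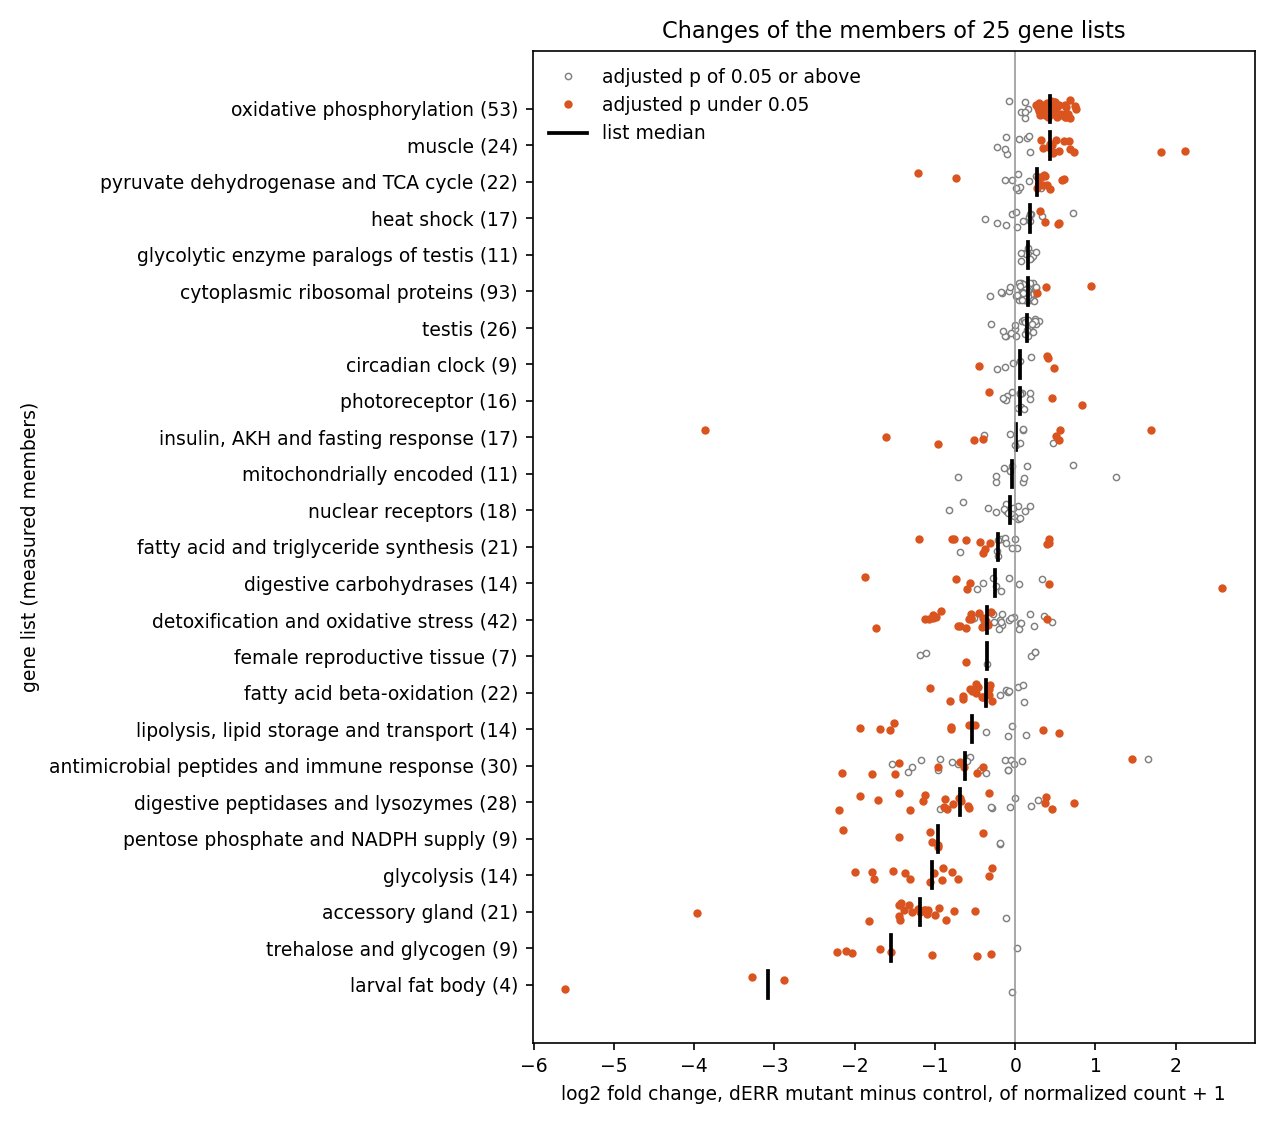
Log2 fold change (mutant minus control) of each measured member of 25 gene lists, with the number of measured members in brackets; filled orange points passed an adjusted p of 0.05 (limma), open grey points did not, and black bars are list medians. Medians run from 0.43 for oxidative phosphorylation and muscle to -1.04 for glycolysis, -1.54 for trehalose and glycogen and -3.08 for the larval fat body genes.

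The largest decreases included larval serum protein, metabolic enzyme and seminal fluid genes. The storage protein gene Lsp2 (FBgn0002565; 3L, 12122492 to 12124796, dm3) changed by -5.61 ± 0.34 (log2, SE), from 1727 ± 474 to 37.5 ± 21.0 normalized counts (SD, n = 3 each). The sorbitol dehydrogenase Sodh-1 changed by -4.97 ± 0.14, the accessory gland gene Acp54A1 by -3.97 ± 0.41, CG9914 by -3.45 ± 0.12, Lsp1beta by -3.28 ± 0.38 and Sfp79B by -2.80 ± 0.36. CG11594 and CG3699 changed by -2.73 ± 0.08 and -2.73 ± 0.11. Among the largest increases were CG13215 at 3.38 ± 0.22, CG6115 at 1.38 ± 0.11, the Zasp family gene CG14168 (Zasp67) at 1.25 ± 0.15 and the cuticle protein gene Cpr66D at 1.22 ± 0.13. The G protein-coupled receptor gene mthl7, which lies 2846 bp from ERR, rose by 1.85 ± 0.30 (adjusted p = 1.58e-03, limma), a call that ended with a robust variance prior (adjusted p = 6.37e-02). CG7979, whose span overlaps that of ERR by 10 bp and which was singled out after its values were seen, changed by -1.36 ± 0.12 (adjusted p = 2.38e-05, limma).

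**Figure D3:**
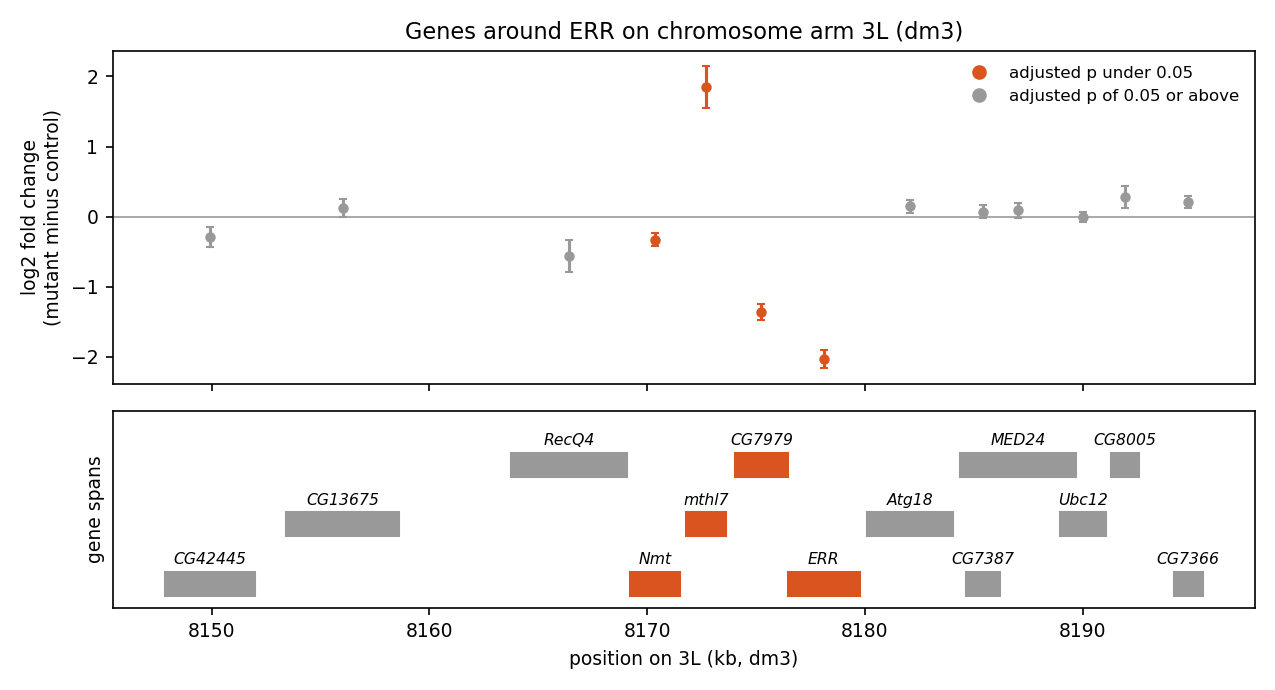
Genes around ERR on chromosome arm 3L in dm3 coordinates: log2 fold change (mutant minus control) with SE above, gene spans in kb below, with orange for an adjusted p under 0.05 (limma) and grey for the rest. ERR (-2.03) and CG7979 (-1.36) are lower, mthl7 (1.85) is higher, Nmt is slightly lower (-0.33), and the genes on the other side of ERR have adjusted p-values above 0.05.

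In the authors' deposited comparison, 1762 genes had an adjusted p under 0.05, 585 higher and 1177 lower. Of these, 1654 were also among the 1851 called here, all in the same direction. The log2 fold changes of both analyses had a Pearson r of 0.980 across genes, which are not independent replicates, and both rest on the same libraries.

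Each library was compared by limma with a trended variance on log2(normalized count + 1), with Benjamini-Hochberg adjustment over all genes. The share of lower genes among calls was 66.7% with the deposited scaling, 53.4% without the 20 most abundant genes in the library size (935 higher, 1072 lower), 54.0% with quantile normalization (919 and 1080) and 43.4% with library size alone (1293 and 992). With scaling to ribosomal protein genes it was 92.8% (187 and 2407), a setting in which the median of all genes was -0.181 (0.003 with the deposited scaling), so directions of small changes are relative to the scaling. The number of higher genes was 330 without control replicate 3 and 382 without mutant replicate 3. Heat treatment and loss of ERR coincide in these groups and cannot be separated, and the labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.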

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

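No test for single outlying libraries was applied to groups of 3, and the patterns weighed here were chosen by reading the results. Tests of chance splits and of scaling were set out before their results were seen, but quantile normalization and scaling to ribosomal protein genes joined the scalings after the data were seen. The tests of tissue share, of heat, of placement near ERR and of reads counted in mthl7 or CG7979 were chosen after the changes they concern were seen.

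The real split of the 6 libraries called 1851 genes, and the highest of the other 9 splits called 0 (limma; 155 to 551 genes at an unadjusted p under 0.05). The real split was thus the only 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

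Seminal fluid genes fell together in mutant flies, with 20 of 21 members of the accessory gland list lower. The scaling of the libraries does not account for it, since at least 20 members were called lower under each of 5 scalings. A smaller share of accessory gland RNA as the whole cause would lower its members alike if all were made by the same cells only. Yet 6 members lay over 3 SE from the list's median, from Acp32CD at -0.11 to Acp54A1 at -3.97, so the members did not fall equally. Where each member is made was not examined, so a smaller share of gland RNA cannot be told apart. Lower output of single genes was not tested. The heat treatment instead of the loss of ERR cannot be told apart, because each mutant library was heated and no control was. Of the heat shock list, 4 members were called higher, among them the overlapping Hsp22 and Hsp67Bb. Their level on day 6 of adult life cannot decide this, because the heat was given earlier, on days 5 and 6 after egg laying. An effect of ERR loss on accessory gland transcription or size stays open and was not tested.

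Nuclear oxidative phosphorylation and muscle genes rose together, each with a median of 0.43. A larger share of RNA from all muscle as the whole cause would raise muscle genes alike, but 9 of 24 members lay over 3 SE from the median. The abundant muscle genes Mhc and sls, named after their values were seen, had log2 changes of 0.18 and -0.11 (adjusted p = 0.433 and 0.755, limma). The list mixes flight muscle genes such as Act88F and TpnC4 with others, so a larger share of a single muscle type cannot be told apart by this spread. A lower share of another tissue would raise photoreceptor and testis genes as much, whereas the oxidative phosphorylation median lay above theirs by 0.32 (95% interval 0.25 to 0.40, bootstrap over genes, which are not independent). The scaling of the libraries cannot be told apart for part of the rise, since scaling to ribosomal protein genes left 22 of 53 members called higher. A response to ERR loss or to heat stays open, untested.

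Close to ERR, mthl7 rose by 1.85 and CG7979 (Uxs) fell by 1.36 on the log2 scale. Chance placement of called genes cannot be told apart: 1.12% of 12928 genes had 2 or more genes changed at least 2-fold among their 4 nearest, but this criterion was taken from the neighbours of ERR themselves, and the fall of CG7979 need not be separate from that of ERR. Reads of the normal ERR transcript counted in mthl7 would make it fall, but it rose by 6.2 SE. That value is the same rise that raised the question. In the reference mthl7 lies on the same strand as ERR, so reads of an altered ERR transcript cannot be told apart. The control libraries of mthl7 varied (200, 94.5 and 66.5) and its call ended with a robust variance prior (adjusted p = 6.37e-02, limma). For CG7979, which lies on the opposite strand to ERR in the reference and overlaps it by 10 bp, reads of ERR cannot be told apart. CG7979 lost 0.32 normalized counts for each one ERR lost, but this ratio cannot decide, because it takes no account of how short the overlap is. The strand setting of the counting, which bears on this, is not given. An effect of the engineered alleles on their neighbours may also be at work and was not tested.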

How the results depend on the processing

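ERR stayed lower in all 16 refitted settings, between -2.22 and -1.92 on the log2 scale (adjusted p from 1.97e-07 to 4.42e-05, limma). Of 130 other named genes that passed the test, 96 passed in each of those settings, 34 lost the call in at least one, and 0 changed direction. Of the 1851 called genes, between 1223 and 1848 passed again in the same direction, the fewest without control replicate 3. The DESeq2 Wald test, the edgeR fits and TMM factors were not run, because no count model was fitted; the deposited median-of-ratios scaling and the absence of a filter are already the main setting. No paired analysis was possible because the labels give no pairing. Among simulated 1.5-fold changes, placed in genes above a minimum mean with a shared dispersion, 92.5% were recovered.

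The number of higher genes (617) became 1293 with library size alone, 935 without the 20 most abundant genes and 187 with scaling to ribosomal protein genes, which gave 2407 lower genes in place of 1234. Without one library it ran from 330 (control 3) to 563. The stricter thresholds, which can only remove calls, gave 275 higher and 804 lower genes at an adjusted p of 0.01, and 144 and 688 with a change of at least 1.5-fold.

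Among the metabolic lists, scaling to ribosomal protein genes left 2 pyruvate dehydrogenase and TCA cycle genes, 22 oxidative phosphorylation genes and 0 fatty acid and triglyceride synthesis genes called higher. Without one library, 7 (mutant 3) to 13 TCA cycle genes were higher, and 8 (control 3) to 14 beta-oxidation and 5 (mutant 3) to 8 synthesis genes lower. With an estimated inter-gene correlation no list passed: adjusted p = 0.213 for glycolysis and for the pentose phosphate list, 0.267 for oxidative phosphorylation and beta-oxidation and 0.443 for the TCA cycle and synthesis lists. In all other settings camera kept these 6 lists under 0.05, with 2.18e-02 for synthesis the highest. Fry, which does not compare a list with other genes, gave an adjusted p of 1.27e-03 for glycolysis and for the pentose phosphate list. Its adjusted p was 5.61e-03 for oxidative phosphorylation, 5.73e-03 for beta-oxidation, 2.67e-02 for the TCA cycle list and 7.69e-02 for synthesis.

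Medians of the testis, testis paralog and cytoplasmic ribosomal protein lists, which passed camera in the deposited scaling, turned to -0.03, -0.02 and -0.02 with scaling to ribosomal protein genes. Hnf4, at -0.03 with the deposited scaling, was at 0.008 with upper-quartile scaling, 0.056 with library size, 0.023 without the 20 most abundant genes, 0.011 with quantile normalization and 0.006 without control 1 (-0.076 to 0.006 over the libraries left out). For mt:CoIII these were 0.024 with library size, 0.058 with quantile normalization and up to 0.140 without mutant 2 (-0.220 to 0.140); mt:CoI was at 0.197 with quantile normalization. Scaling to ribosomal protein genes gave Eip75B -0.129, S-Lap1 -0.021 and loopin-1 -0.038. The insulin list turned in camera with the stricter filter (adjusted p = 0.950), with ribosomal scaling (0.595) and without control 1 or mutant 2 (range over the libraries left out 0.613 to 0.974). The mitochondrially encoded list turned with the stricter filter (0.636), library size (0.911) and without control 1 or mutant 1 (range 0.444 to 0.812), and the female reproductive list with ribosomal scaling (0.823). Scaling to ribosomal protein genes shifts all genes together (median of all genes -0.181) and centers the ribosomal protein list by design. The turned medians and single genes in that setting go with this shift. The cause was not tested for the turns in camera or in the other settings.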

Other observations

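Gene families were also grouped by the stem of their current symbols, a choice made after the data were seen, which gave 91 families of at least 8 genes. Of these, 22 had a camera adjusted p under 0.05, 11 lower and 11 higher, and 0 with an estimated correlation. The seminal fluid protein family Sfp fell in 27 of 28 genes, with a median of -0.90 and medians from -1.09 to -0.82 over 5 scalings, beside the fall of the accessory gland list (camera adjusted p = 3.20e-25; adjusted p = 0.50 with an estimated correlation). C-type lectins fell in 8 of 12 genes (median -0.59), led by lectin-24A at -2.05, with 0 higher. Of 28 genes with the stem Spn, which are serpins apart from spinophilin (Spn), 12 fell and 1 rose (median -0.38), with Spn77Bb and Spn77Bc at -1.85 and -1.86 and Spn31A at 0.90. Of 10 Npc genes, which bind or carry sterols, 6 fell, among them Npc2h at -1.62 and Npc2g at -0.97 on the log2 scale. Of 18 neprilysin-like peptidase genes 7 fell (median -0.51). Camera adjusted p-values were 2.87e-06 for lectins, 5.62e-05 for Spn genes, 9.90e-06 for Npc and 1.13e-04 for neprilysin-like genes, and 0.45, 0.45, 0.45 and 0.50 with an estimated correlation.

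Beyond the respiratory chain subunits, 5 of 8 coenzyme Q synthesis genes rose (median 0.28; camera adjusted p = 1.10e-03; adjusted p = 0.50 with an estimated correlation), with COQ7 at 0.43, although 0 were called by limma with scaling to ribosomal protein genes. Of the mitochondrial ribosomal protein genes 4 of 47 mRpL and 3 of 26 mRpS genes rose, with medians of 0.15 and 0.14 that each became -0.04 with that scaling. Over 5 scalings 2 to 14 mRpL and 1 to 6 mRpS genes were called higher, the most with library size alone. Camera gave adjusted p-values of 8.03e-05 and 1.15e-03, and adjusted p = 0.69 for both with an estimated correlation. Of 9 SmydA genes, predicted methyltransferases, 5 rose (median 0.36; camera adjusted p = 1.91e-04; adjusted p = 0.50 with an estimated correlation), and 4 were called higher with scaling to ribosomal protein genes. Cytochrome P450 genes fell in 28 of 82 cases and rose in 1, against 22 and 4 with library size alone and 36 and 1 with scaling to ribosomal protein genes (median -0.25; camera adjusted p = 5.62e-05; adjusted p = 0.50 with an estimated correlation).

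Some large falls cannot be assigned to one gene. Adh and Adhr, which overlap, had levels within 0.20% of each other in each library and both changed by -2.45 on the log2 scale. CG9510 and CG9515 had identical levels and changed by -2.03.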
